A study of Nicotiana tabacum with 12 samples.

How the data were processed

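RNA was sequenced from seedling leaves of Nicotiana tabacum, in 4 groups of 3 libraries taken from the sample labels. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. One table of 69500 genes was used, and per the submitters' processing notes the tools were Salmon and StringTie, with no versions. The aligner settings and genome build were not given in the sources used here, and the annotation release only through the identifier prefix Nitab4.5. Whether reads of both wild types match that reference equally well was not tested. The deposited values were taken as TPM, a transcript share corrected for length, from the tools named and the range of the values. The header names no unit, and FPKM cannot be excluded, since the columns sum to between 334759 and 676862. No pair of libraries held identical values.

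The total of mapped reads is unknown, since TPM keeps no depth. Low values of single genes were checked for whole-read steps, and 40.0 to 74.2% of them fell on steps within 0.05 log2, against 25.1% by chance, so reads were not recovered. Of the genes listed, 19757 were at 0 in every library. Gene descriptions are InterPro domain names from the table itself, and 19827 genes are described only as Unknown. Of the gene identifiers, 0 matched the RefSeq table, so no positions in the genome are given.

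The planned test for counts did not apply to TPM, and the test planned for normalized values was used. Genes with a value of at least 1 in at least 3 libraries were kept (31311), and log2(value + 1) was fitted in limma 3.58.1 (R 4.3.3) with a mean for each of the 4 groups over all 12 libraries, trend and robust settings, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The comparisons were knockout against K326, overexpression against KY, K326 against KY, and the difference of the first 2 effects. These choices, the gene lists and the naming rule were fixed before the data were examined.

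Gene lists were matched to the descriptions by fixed patterns. Of 28 lists, 18 had at least 3 tested genes. Of the 10 others, 7 matched no gene, and the rest had too few. A further 22 lists were written after the descriptions had been seen and serve only the closing observations and the UDP-glycosyltransferase family. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and with an estimated correlation. The fry test, which asks whether the genes of a list move one way, was an alternative. The genes named were all magnesium chelatase genes, the 10 largest rises and falls among called genes whose groups did not overlap, with a mean of at least 5 TPM in the higher group and an informative description, the 2 members of each list with the smallest p, and 5 genes per direction for the difference.

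Alternatives planned were quantile normalization, no filter, a mean of at least 5, a pseudocount of 0.1, the 6 compared libraries alone, a fold of at least 2, the replicate number as a block, the other wild type as reference, and each library left out. Median scaling, with each library divided by its median ratio to the mean profile over 20130 genes at 1 or more in all libraries, was added after the data had been seen. It kept 30621 genes. Sums of chelatase copies were compared with exact permutation tests. Genes were called on in a wild type at 2 or more and off at 0.2 or less in all its libraries.

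The fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For knockout against K326 it recovered 33% and 92% of them on 30438 genes with the library offsets left in, and 55% and 93% on 29912 genes with offsets removed. For overexpression against KY it recovered 18% and 95% on 30476 genes, and 64% and 96% on 29887 genes. False calls were 18 of 143 and 8 of 156 for knockout against K326, offsets left in and removed, and 8 of 121 and 9 of 169 for overexpression against KY. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.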

Results

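Gene expression was measured by RNA sequencing of seedling leaves of tobacco (Nicotiana tabacum), an allotetraploid that carries homeologous gene copies from both of its ancestral genomes. The 12 libraries formed 4 groups of 3: wild type KY, wild type K326 (a flue-cured cultivar), a knockout line named Q18 and an overexpression line named YOE. The study addressed how NtCISZOG, an enzyme of the cis-zeatin O-glucosyltransferase type that attaches glucose to a cytokinin, acts on chlorophyll content and on NtChlH, the H subunit of magnesium chelatase. This chelatase inserts magnesium into protoporphyrin IX at the first step that leads to chlorophyll alone. The sample labels did not name the background of either line. The design text named K326-gk-8 and KY-OE-31, and those wild types served as references for the knockout and the overexpression line. Whether these are the lines labelled Q18 and YOE was not given in the sources used here. The raw data name the YOE libraries G31, which shares its number with KY-OE-31.

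The deposited TPM values summed to 481023 ± 23280 in KY, 585544 ± 68735 in K326, 652723 ± 38263 in the knockout and 410967 ± 77649 in the overexpression libraries (SD, n = 3 each, as for all values below given with ±). Single libraries ranged from 334759 to 676862. The median log2 difference over the 31311 tested genes was 0.24 for knockout minus K326, -0.11 for overexpression minus KY and 0.39 for K326 minus KY. Dividing each library by a median ratio brought these medians to 0.02, -0.01 and 0.02. Both scales were therefore used.

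After median scaling, the first principal component held 40.7% of the variance and separated the KY libraries from the 9 others. The second component held 28.1% and separated the overexpression libraries from the rest. The mean correlation across genes between overexpression and K326 libraries was 0.921, against 0.877 between overexpression and KY libraries. KY and K326 libraries correlated at 0.914, so by this measure overexpression was about as far from K326 as KY was. Overexpression libraries correlated with each other at 0.944. K326 and knockout libraries correlated at 0.966. Genes are not independent replicates, so these correlations describe the libraries only.

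**Figure D1:**
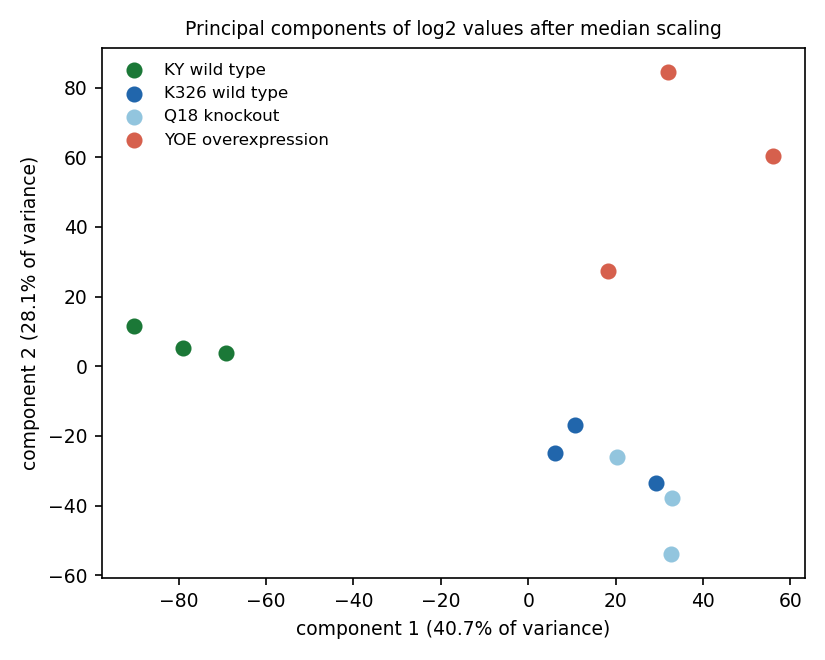
The first 2 principal components of the log2 values after median scaling, 1 point per library, coloured by group, with the axes in component units. The KY libraries sit apart on component 1 (40.7% of the variance), the overexpression libraries lie highest on component 2 (28.1%), and K326 and knockout libraries lie close together.

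NtCISZOG was not identified here: no gene description named a zeatin O-glucosyltransferase, and 0 of the gene identifiers matched the RefSeq gene table. Its level, which could bear on the labels without settling both, is therefore not given, and "knockout" and "overexpression" stand for the libraries labelled so. The wider UDP-glycosyltransferase family, to which such enzymes belong, had 340 members, of which 127 were tested. None of these was called in knockout against K326. Against KY, 10 were higher and 30 lower in the overexpression libraries (17 and 37 when adjusted over the list alone). Which member, if any, is NtCISZOG was not given in the sources used here.

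A group of genes chosen after the values were seen also bears on the labels. There were 87 genes at 2 TPM or more in every K326 library and at 0.2 or less in every KY library, and 13 genes with the opposite state. Of the 87, the overexpression libraries had 85, 82 and 85 at 1 TPM or more, and the knockout libraries had 85, 85 and 86. Of the 13, the overexpression libraries had 0, 1 and 1 at that level, and each knockout library had 0. At these genes the libraries labelled as overexpression went with K326 and not with KY, the reference taken from the design text. Every direction given below for overexpression against KY is thus drawn between libraries that also differ at these genes. The likeness to K326 was not confined to them. Of 2118 genes higher in overexpression than in KY, 1430 were also higher in K326. Of 3603 lower genes, 706 were also lower, and both comparisons share the KY libraries. Against KY, an effect of the line could therefore not be told apart from a difference in background. K326 is given as a second reference for the gene counts, the largest changes and the lists.

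**Figure D2:**
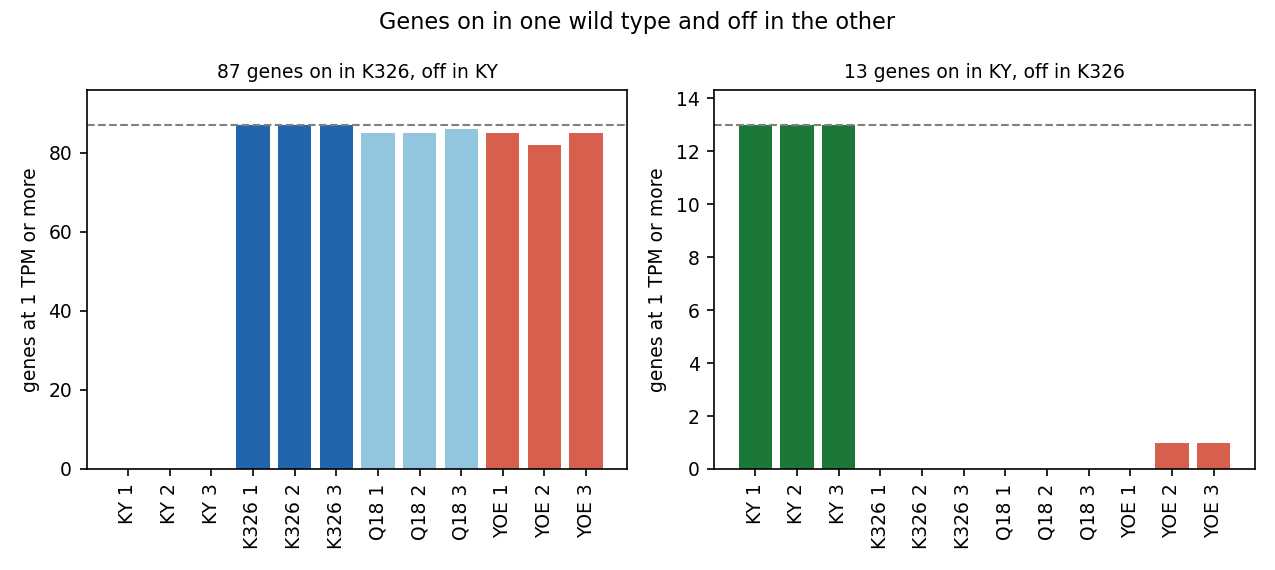
Number of genes at 1 TPM or more in each library (bars), for 87 genes on in K326 and off in KY (left) and 13 genes on in KY and off in K326 (right), with the dashed line at the full set. Overexpression libraries had 82 to 85 of the 87 and 0 or 1 of the 13.

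The magnesium chelatase genes were the main target of the comparison, and 5 were tested. Both ChlH copies, Nitab4.5_0005195g0040 and Nitab4.5_0010636g0020, had nearly equal means in the knockout and in K326. The first stood at 57.1 ± 21.5 TPM in the knockout and 56.9 ± 11.1 in K326 (log2 change -0.04, limma adjusted p = 0.931). The second stood at 78.5 ± 35.2 and 73.8 ± 13.2 TPM (log2 change 0.01, adjusted p = 0.986; SD, n = 3). None of the 5 genes was called in the knockout by limma, over all genes or adjusted over the list alone, and median scaling also gave none.

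Against KY, the overexpression libraries had 2 chelatase genes higher and 2 lower, over all genes and adjusted over the list alone. The ChlH copy Nitab4.5_0005195g0040 was near 0 in KY, at 0.06, 0.26 and 0 TPM, and stood at 39.9 ± 6.32 TPM in the overexpression libraries (log2 change 5.20, limma adjusted p = 8.6e-10). The ChlH copy Nitab4.5_0010636g0020 was lower, at 50.5 ± 9.25 TPM against 241 ± 29.0 (log2 change -2.24, adjusted p = 3.5e-05). The D-type subunit showed the same division. Its copy Nitab4.5_0000733g0210 was at 0.03, 0.08 and 0 TPM in KY and 8.36 ± 0.544 in overexpression, while Nitab4.5_0001663g0090 was lower (26.7 ± 2.14 against 11.1 ± 1.07). The I subunit, Nitab4.5_0006237g0030, at 49.6 ± 4.49 and 39.3 ± 1.15 TPM, was not called.

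K326 differed from KY at the same 4 copies in the same directions. Its ChlH copies stood at 56.9 ± 11.1 and 73.8 ± 13.2 TPM, with log2 changes against KY of 5.70 and -1.70 (limma adjusted p = 2.5e-10 and 4.7e-04). Its lower D-type copy, Nitab4.5_0001663g0090, had an adjusted p of 0.0081, which reached 0.0526 when 1 library was left out. Against K326 with median scaling, neither ChlH copy was called in the overexpression libraries (log2 changes 0.16 and 0.12, adjusted p = 0.775 and 0.858). Summed over both copies, ChlH was 241 ± 28.9 TPM in KY, 131 ± 24.2 in K326, 136 ± 56.7 in the knockout and 90.4 ± 15.5 in overexpression. As deposited the overexpression sums (76.8 to 107 TPM) lay below those of K326 (116 to 159). With median scaling the direction turned, at 127 ± 38.9 in overexpression against 113 ± 27.4 in K326 and 295 ± 55.4 in KY. On the scaled sums, a two-sided exact permutation test gave p = 0.1 for overexpression and for K326 against KY, the smallest p that 3 against 3 allows, and p = 0.6 for overexpression against K326. Reads of such copies can be split or moved between them, so single copies are less certain than their sum.

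**Figure D3:**
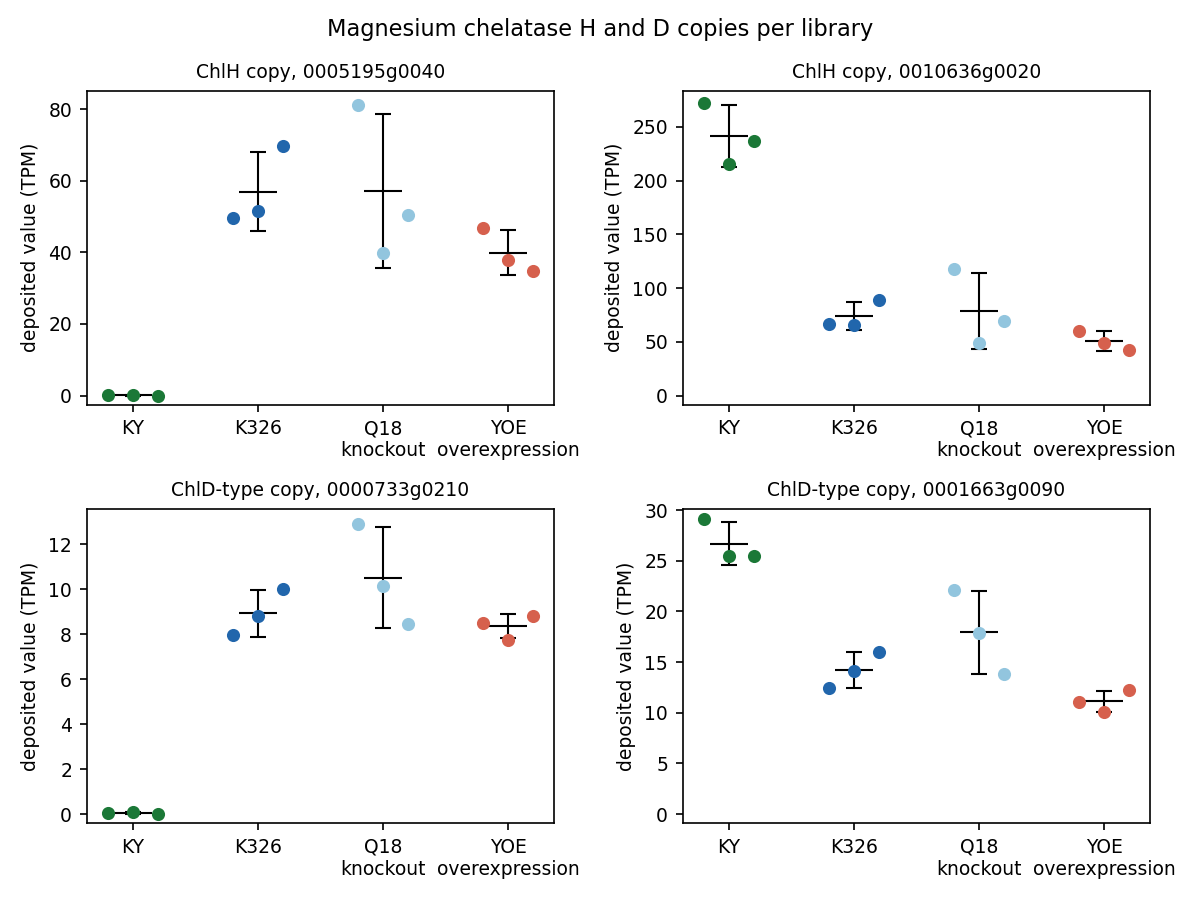
Deposited TPM of the ChlH and ChlD-type copies of magnesium chelatase, 1 point per library, with the group mean (horizontal line) and SD (bars, n = 3). In KY 1 copy of each pair was near 0 and the other was at its highest (241 TPM for ChlH), while all other groups expressed both.

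The knockout differed from K326 in few genes. A gene with a triose-phosphate transporter domain, Nitab4.5_0001884g0050, a family that moves sugar phosphates across the plastid envelope, was higher at 38.8 ± 4.15 TPM against 9.44 ± 2.91 (log2 change 1.97, limma adjusted p = 0.035). Nitab4.5_0001739g0060, with the C-terminal domain of coiled-coil protein 109, a domain of mitochondrial calcium uniporters, stood at 21.9 ± 6.23 against 6.75 ± 1.74 TPM (log2 change 1.55). A glycoside hydrolase of family 14, the beta-amylase family, Nitab4.5_0001255g0020, was lower at 17.1 ± 0.477 against 68.1 ± 12.6 TPM (log2 change -1.92, adjusted p = 0.012). Outside the naming rule, and chosen after their values were seen, Nitab4.5_0002073g0040 (3.81 to 14.2 TPM) and Nitab4.5_0002637g0020 (1.03 to 4.38 TPM) were higher, and Nitab4.5_0003884g0100 (3.03 to 0.517 TPM) was lower.

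These 6 genes, 4 higher and 2 lower, were all that passed, while 2543 had an unadjusted p under 0.05. In simulated data for this comparison, with 100 genes changed 2-fold, 100 changed 4-fold and the library offsets left in, 18 of 143 calls were false. That share does not carry over to so few real calls, so the simulation does not say how many of the 6 genes may be false. With median scaling limma called 0 genes (2075 at unadjusted p), as did quantile normalization (2085), and the 3 genes named by the rule had log2 changes of 1.68, 1.27 and -2.17 with adjusted p of 0.0992, 0.144 and 0.112. The count was 12 without K326 replicate 1 (8 with median scaling), 3 without knockout replicate 2 and 0 without knockout replicate 3.

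Of the 18 gene lists tested in the knockout, 3 lay lower than other genes, although no member of any list was called. Their medians were positive as deposited, so by the median they lay lower on that scale only relative to other genes. Their mean log2 changes as deposited were -0.01 for light-harvesting, -0.08 for phenylpropanoid and 0.08 for cell division genes. The medians turned negative with median scaling (-0.25 for light-harvesting, -0.26 for phenylpropanoid and -0.16 for cell division genes). The light-harvesting chlorophyll a-b binding proteins (88 genes), which carry antenna chlorophyll, had a median log2 change of 0.03, below the median of 0.24 over all genes (camera adjusted p = 6.9e-07; adjusted p = 0.869 with an estimated correlation). For phenylpropanoid and flavonoid synthesis (19 genes) the median was 0.0040 (adjusted p = 6.6e-06; 0.681 as adjusted p with an estimated correlation). Cell division genes, here mainly histones (63 genes), had a median of 0.08 (adjusted p = 0.0352; adjusted p = 0.869 with an estimated correlation). Chlorophyll biosynthesis (48 genes, adjusted p = 0.0864) and the cytokinin genes (26 genes, 0.396) were not called. With median scaling 6 lists were called, with cytosolic ribosomal proteins (adjusted p = 5.1e-07), chlorophyll biosynthesis (0.0298) and carotenoid genes (0.0237) added, each at adjusted p = 0.847 with an estimated correlation. Adjusted over the list alone, calls were few: 2 auxin genes, 1 senescence gene, 1 heat shock gene and 1 vascular gene were higher, and 2 vascular genes were lower. The number of lists called was 8 without K326 replicate 2 or knockout replicate 1, 5 without knockout replicate 3, 1 without K326 replicate 1 and 0 without knockout replicate 2.

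The overexpression libraries differed from KY in 5721 genes, 2118 higher and 3603 lower. Among the largest rises beside ChlH were a lipid transfer protein, Nitab4.5_0000212g0010 (61.2 ± 36.1 TPM against 0.0467 ± 0.0451), a factor of the elongation factor G type, Nitab4.5_0000147g0070 (46.0 ± 10.4 against 0.147 ± 0.150), and an EF-hand calcium-binding protein, Nitab4.5_0005031g0050 (40.4 ± 11.9 against 0.02 ± 0.0346). A ubiquitin-conjugating enzyme, Nitab4.5_0003779g0060, and translation initiation factor 1A, Nitab4.5_0003779g0110, were listed at 0 in all 3 KY libraries and stood at 60.2 ± 22 and 42.7 ± 12.3 TPM in overexpression. The other largest rises were an NmrA-like protein (Nitab4.5_0000733g0110), a dihydroneopterin aldolase of folate synthesis (Nitab4.5_0008674g0010) and 2 triose phosphate/phosphoenolpyruvate translocators (Nitab4.5_0000006g0100 and Nitab4.5_0002137g0140), whose replicates spread widely (67.8 ± 67.9 and 82.1 ± 91.3 TPM).

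The largest falls included a family 18 chitinase, Nitab4.5_0000416g0240 (1.21 ± 0.370 TPM against 51.8 ± 18.1; log2 change -4.53, limma adjusted p = 2.1e-08), and its numbered neighbour Nitab4.5_0000416g0250. A transcriptional coactivator of the PC4 type, Nitab4.5_0001310g0060, was lower (5.52 ± 3.65 against 111 ± 19.5 TPM). So was a pyruvate, phosphate dikinase-type gene, Nitab4.5_0000059g0230 (5.67 ± 3.01 against 112 ± 10.1). The others were a major latex protein (Nitab4.5_0002618g0020), a transposase (Nitab4.5_0000386g0150), a Myb-like gene (Nitab4.5_0002241g0010), a potato inhibitor I-type proteinase inhibitor (Nitab4.5_0003154g0030), a family 14 glycoside hydrolase (Nitab4.5_0000185g0250) and a glutaredoxin (Nitab4.5_0001943g0010). All 10 named rises and all 10 named falls were also called in K326 against KY in the same direction. Against K326 with median scaling, 0 of the rises and 2 of the falls were called in limma: the dikinase-type gene (log2 change -1.19, adjusted p = 0.0119) and the glutaredoxin (-0.61, 0.0237). As deposited, several of the rises lay below every K326 library. The EF-hand gene stood at 27.3 to 50.3 TPM against 86.3 to 94.5, and the lipid transfer protein at 26.7 to 98.8 against 123 to 159. The elongation factor G-type gene and the triose phosphate/phosphoenolpyruvate translocators overlapped K326.

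With median scaling the overexpression libraries differed from KY in 5474 higher and 5353 lower genes, so the split moved from 37.0% to 50.6% higher. The count as deposited was 3310 without KY replicate 1 and 3543 without KY replicate 3, and the share of higher genes was 50.9% without overexpression replicate 2 and 25.6% without replicate 3. Against K326, 592 genes were higher and 11551 lower as deposited, and 1749 higher and 1450 lower with median scaling. That comparison rested on single libraries. As deposited its total of 12143 went to 2742 and 5092 without K326 replicate 2 and 3, and to 3326 without overexpression replicate 2. The scaled total of 3199 went to 1368 and 1018 without K326 replicate 2 and 3, and to 5241 and 854 without overexpression replicate 1 and 2.

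**Figure D4:**
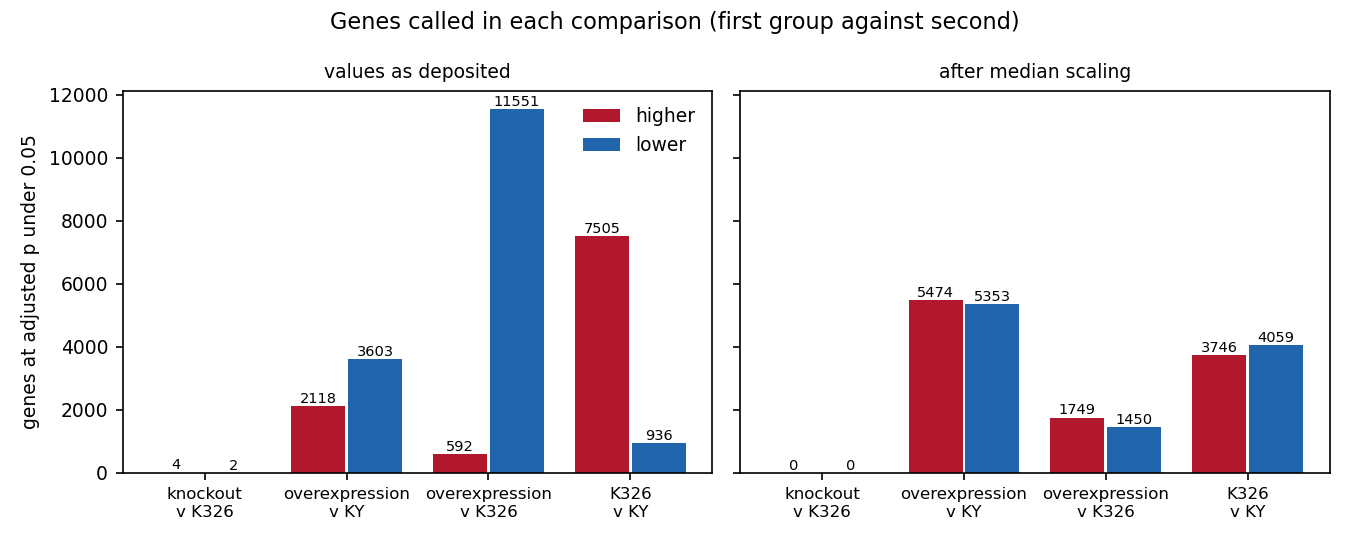
Number of genes higher (red) or lower (blue) in the first group at a limma adjusted p under 0.05, for values as deposited (left) and after median scaling (right). The one-sided counts as deposited (7505 higher and 936 lower in K326 against KY) became even after scaling (3746 and 4059).

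In 3 lists of photosynthesis and pigment genes, more of the called members were lower than higher in the overexpression libraries than in KY, and many members were not called. Of 88 light-harvesting chlorophyll a-b binding genes, 19 were lower and 1 higher (27 and 1 when adjusted over the list alone, 10 and 1 with median scaling), among them Nitab4.5_0000471g0030 (106 ± 41.4 TPM against 433 ± 21.9) and Nitab4.5_0003611g0080 (1.63 ± 0.631 against 11.9 ± 3.56). The list lay lower than other genes (camera adjusted p = 4.5e-05; adjusted p = 0.752 with an estimated correlation). Of 33 Calvin cycle genes, 13 were lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 0.00428; adjusted p = 0.667 with an estimated correlation). One was Nitab4.5_0001112g0030 (135 ± 7.83 against 375 ± 29.8 TPM), and some members carry a uridine kinase domain, an enzyme of nucleotide salvage outside this cycle. Of 14 carotenoid genes, 7 were lower and 0 higher (9 and 0 when adjusted over the list alone), such as the squalene/phytoene synthase gene Nitab4.5_0000091g0360 (83.0 ± 30.2 against 191 ± 18 TPM). That list was lower too (camera adjusted p = 0.00428; adjusted p = 0.605 with an estimated correlation).

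Chlorophyll biosynthesis had 11 lower and 2 higher of 48 genes, over all genes and adjusted over the list alone, and missed the threshold as a list (camera adjusted p = 0.0517). Chlorophyll breakdown had 9 lower and 3 higher of 23 (11 and 3 when adjusted over the list alone; camera adjusted p = 0.222). Its members included a lower pheophorbide a oxygenase gene, Nitab4.5_0002162g0210 (24.3 ± 4.63 against 80.7 ± 5.06 TPM), and a higher chlorophyllase gene, Nitab4.5_0011519g0020 (22.7 ± 18.3 against 0.343 ± 0.180 TPM). Nitrate assimilation had 9 lower and 2 higher of 26, over all genes and adjusted over the list alone (camera adjusted p = 0.367). Of its genes, 2 of the nitrate reductase type were lower, Nitab4.5_0002857g0010 (19.8 ± 4.71 against 71.8 ± 3.48 TPM) and Nitab4.5_0023821g0010 (32.1 ± 8.84 against 121 ± 4.44 TPM). Median scaling turned this split to 9 higher and 7 lower. Cytokinin synthesis and breakdown had 4 higher and 5 lower of 26 (4 and 6 when adjusted over the list alone; camera adjusted p = 0.952), and 8 higher and 6 lower with median scaling. Senescence genes had 4 each way of 20 (5 higher and 6 lower when adjusted over the list alone; 0.623), and phenylpropanoid genes had 1 higher and 2 lower of 19, also when adjusted over the list alone (0.479), and 2 higher and 1 lower with median scaling. The medians of the cytokinin (-0.26), senescence (-0.16) and magnesium chelatase lists (-0.33; camera adjusted p = 0.350) were negative while the test pointed higher.

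Other lists lay higher. Cell division genes had 20 higher and 1 lower of 63 (23 and 1 when adjusted over the list alone), including the histone H2B genes Nitab4.5_0006213g0010 and Nitab4.5_0001163g0030, listed at 0 in each KY library and at 2.58 ± 0.436 and 2.83 ± 1.31 TPM in overexpression (camera adjusted p = 8.4e-10; adjusted p = 0.459 with an estimated correlation). The abscisic acid list, mostly late embryogenesis abundant proteins and dehydrins that accumulate in drying tissue, had 19 higher and 9 lower of 72 (25 and 9 when adjusted over the list alone; camera adjusted p = 7.0e-05; adjusted p = 0.605 with an estimated correlation). Vascular markers, here phloem protein 2-like and sieve element occlusion genes, had 8 higher and 2 lower of 36 (9 and 3 when adjusted over the list alone, camera adjusted p = 0.00308, adjusted p = 0.605 with an estimated correlation). They were matched by domain name alone, and whether they mark vascular tissue was not tested. Of the pathogenesis-related proteins 1 of 19 was higher and of the pollen and flower markers 1 of 4, also when adjusted over each list alone (camera adjusted p = 0.0248 and 0.0437; adjusted p = 0.459 and 0.605 with an estimated correlation). Among cytosolic ribosomal proteins 1 of 24 was higher as deposited, 0 when adjusted over the list alone and 15 with median scaling (0.029; adjusted p = 0.752 with an estimated correlation).

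Heat shock proteins had 12 lower and 1 higher of 69 (13 and 1 when adjusted over the list alone; camera adjusted p = 0.0124; adjusted p = 0.752 with an estimated correlation). Auxin response, mainly ARG7-type genes, had 11 lower and 1 higher of 45, also when adjusted over the list alone (camera adjusted p = 0.0437; adjusted p = 0.667 with an estimated correlation). In all, camera called 11 of the 18 lists, 6 higher and 5 lower, and none with an estimated correlation. With median scaling the pathogenesis-related (adjusted p = 0.175), pollen and flower (0.0992) and auxin lists (0.0562) lost their calls. On that scale cell division genes had 34 higher and 1 lower, the abscisic acid list 29 and 9, the vascular list 14 and 3, the Calvin cycle 4 and 12, carotenoid genes 0 and 8, and heat shock proteins 6 and 15.

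The lists were also read against K326 with median scaling, a choice made after the data were seen. There 13 cell division genes were higher and 0 lower (5 and 11 as deposited; scaled camera adjusted p = 3.5e-09; adjusted p = 0.641 with an estimated correlation). The abscisic acid list had 10 higher and 4 lower (1 and 18 as deposited; scaled adjusted p = 0.0316; adjusted p = 0.737 with an estimated correlation). Vascular markers had 12 higher and 1 lower (9 and 9 as deposited; scaled adjusted p = 5.8e-05; adjusted p = 0.0858 with an estimated correlation), and cytokinin genes 6 and 1 of 25 (4 and 7 of 26 as deposited; 0.0156; adjusted p = 0.118 with an estimated correlation). Light-harvesting genes had 0 higher and 1 lower of 88 (0 and 24 as deposited) and carotenoid genes 2 and 0 (0 and 5 as deposited), with the test pointing higher and neither list called (0.0834 and 0.132). Calvin cycle genes had 0 higher and 5 lower (0 and 15 as deposited), heat shock proteins 0 and 6 (0 and 27) and auxin genes 1 and 4 (0 and 11), and none of these lists was called on either scale. Chlorophyll biosynthesis had 2 higher and 1 lower (0 and 8 as deposited) and cytosolic ribosomal proteins 2 and 0 (0 and 6 as deposited), and both were higher as lists on the scaled values only (8.0e-04 and 0.0172; adjusted p = 0.737 with an estimated correlation for each). Pathogenesis-related genes (4 higher and 0 lower of 16 scaled, 3 and 1 of 19 as deposited) and pollen and flower markers (3 and 0 of 4 scaled, 2 and 0 as deposited) were higher on both scales, and their calls held with an estimated correlation as deposited (adjusted p = 0.0213 with an estimated correlation for each) but not scaled (adjusted p = 0.145 with an estimated correlation for each).

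Of the other lists against K326, chlorophyll breakdown had 2 higher and 0 lower of 23 with median scaling (1 and 12 as deposited), nitrate assimilation 1 and 4 of 26 (0 and 13), senescence genes 3 and 2 of 20 (1 and 10) and phenylpropanoid genes 1 and 0 of 18 (0 and 6 of 19), and none of these lists was called on either scale. Of the list genes named above, the light-harvesting genes Nitab4.5_0000471g0030 and Nitab4.5_0003611g0080 and the pheophorbide a oxygenase gene Nitab4.5_0002162g0210 were lower than in K326 as deposited (log2 changes -1.24, -0.95 and -0.70) and not called with median scaling (-0.57, -0.49 and -0.05). The Calvin cycle gene Nitab4.5_0001112g0030 and the phytoene synthase-type gene Nitab4.5_0000091g0360 were called on neither scale. Both nitrate reductase-type genes were lower on both scales (scaled log2 changes -0.65 and -0.75, limma adjusted p = 0.016 and 0.00929). The H2B gene Nitab4.5_0006213g0010 was higher on both scales (scaled log2 change 1.39), and Nitab4.5_0001163g0030 only as deposited (scaled adjusted p = 0.0512).

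The 2 wild types set the scale of cultivar differences. K326 had 7505 genes higher and 936 lower than KY, and with median scaling 3746 and 4059, so that the share of higher genes went from 88.9% to 48.0%. The largest rises were mostly those of the overexpression libraries, led by the lipid transfer protein Nitab4.5_0000212g0010 (136 ± 19.5 TPM against 0.0467 ± 0.0451; log2 change 7.03, limma adjusted p = 6.3e-09) and the EF-hand protein Nitab4.5_0005031g0050 (91.4 ± 4.46 against 0.02 ± 0.0346 TPM). They also held a papain-type cysteine protease, Nitab4.5_0000681g0080 (52.2 ± 19.9 against 0.09 ± 0.131 TPM). The largest falls were led by 2 DnaJ-domain genes, Nitab4.5_0011198g0010 (1.81 ± 0.615 against 45 ± 6.22 TPM) and Nitab4.5_0005707g0010 (1.80 ± 0.522 against 37.0 ± 6.86 TPM), then the transposase Nitab4.5_0000386g0150 and the chitinase Nitab4.5_0000416g0240, and they held a MADS-box gene, Nitab4.5_0014584g0010 (0.0133 ± 0.0231 against 9.14 ± 0.612 TPM). The aminotransferase gene Nitab4.5_0000302g0060 (2.97 ± 5.05 against 17.3 ± 1.02 TPM) lost its call with 1 library left out (highest adjusted p 0.156). The count of genes was 3111 without KY replicate 1, 3579 without KY replicate 3 and 3013 without K326 replicate 2 (3938, 4581 and 4481 of 7805 with median scaling).

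Among the lists, light-harvesting genes lay lower in K326 relative to other genes, with 5 higher and 3 lower of 88 as deposited (2 each way when adjusted over the list alone) and 2 higher and 18 lower with median scaling (camera adjusted p = 2.5e-08; adjusted p = 0.626 with an estimated correlation). Chlorophyll biosynthesis did likewise, with 5 higher and 6 lower of 48, over all genes and adjusted over the list alone, and 4 higher and 16 lower with median scaling (camera adjusted p = 1.8e-05; adjusted p = 0.626 with an estimated correlation). Carotenoid genes (0 higher and 2 lower of 14, or 0 and 1 when adjusted over the list alone) and Calvin cycle genes (5 and 3 of 33, also when adjusted over the list alone) were lower as lists (0 and 9 for carotenoid genes with median scaling; camera adjusted p = 3.9e-04 and 0.00181; adjusted p = 0.626 with an estimated correlation for each). With median scaling the Calvin cycle split was 5 higher and 9 lower. Of its higher members, Nitab4.5_0000646g0130 and Nitab4.5_0001622g0020 were uridine kinase-type genes of nucleotide salvage.

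Cytosolic ribosomal proteins were higher in K326, with 15 of 24 up and 0 down (19 and 0 when adjusted over the list alone, 7 and 1 with median scaling; camera adjusted p = 0.00526; adjusted p = 0.650 with an estimated correlation). Cell division genes had 31 higher and 2 lower of 63 (35 and 2 when adjusted over the list alone, 12 and 2 with median scaling), and the abscisic acid list had 31 higher and 1 lower of 72 (36 and 1 when adjusted over the list alone, 22 and 3 with median scaling). For both the camera adjusted p was 0.0181 and the adjusted p = 0.638 with an estimated correlation. The dehydrin Nitab4.5_0000588g0250 reached 1088 ± 397 TPM against 232 ± 65.3. Auxin response (3 higher and 1 lower of 45, or 1 and 0 when adjusted over the list alone), cytokinin genes (2 and 1 of 26, or 1 and 1), pollen and flower markers (0 of 4) and phenylpropanoid genes (0 of 19) were lower as lists, at camera adjusted p from 0.00206 to 0.0333 and adjusted p from 0.626 to 0.638 with an estimated correlation. The medians of the cytokinin (0.05) and phenylpropanoid lists (0.24) were positive, below that of all genes. With median scaling the auxin split was 1 higher and 5 lower and the cytokinin split 1 and 6, and the cell division (adjusted p = 0.106), auxin (0.178), phenylpropanoid (0.178) and pollen lists (0.202) lost their calls. In all 11 of 18 lists were called, 3 higher and 8 lower, and none with an estimated correlation.

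Of the 2118 genes higher in overexpression than in KY, 1430 (67.5%) were also higher in K326 than in KY, against 508 for independent lists. Of the 3603 lower genes, 706 (19.6%) were also lower in K326, against 108. Genes called in opposite directions numbered 1 and 44. With median scaling the shared genes were 2273 of 5474 and 2895 of 5353, against 670 and 710 for independent lists. Both comparisons use the KY libraries, and unchanged groups simulated against those controls gave a correlation of fold changes of 0.501 where 0.691 was observed, and a covariance of 0.0404 (at most 0.0427 over 100 draws) where 0.272 was observed. With 3 KY libraries the controls could not be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls.

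The effect in the overexpression libraries minus the effect in the knockout differed from 0 in 2750 genes, 581 positive and 2169 negative (2539 and 2392 with median scaling, which moved the share of positive genes from 21.1% to 51.5%). The smallest p-values belonged to the EF-hand gene Nitab4.5_0005031g0050 (difference 5.51, SE 0.32, limma adjusted p = 5.5e-08) and the transposase gene Nitab4.5_0000386g0150 (-4.17, SE 0.24, 5.5e-08). ChlH copy Nitab4.5_0005195g0040 was among the 5 leading positive genes (5.24, SE 0.36). Regrouping the knockout and K326 libraries while overexpression and KY stayed apart gave 1023 to 4901 such genes over 19 other splits. Of the 6 genes called in the knockout, 3 were called the other way in overexpression: 1 was higher there and lower in the knockout, and 2 the reverse, against 0.135 and 0.460 for independent lists. The rest of the shared calls were 1 gene higher and 1 lower in both, against 0.271 and 0.230. The count was 1135, 1353 and 1280 without KY replicate 1, 2 and 3. It was 1568 without K326 replicate 1, 1484 and 1515 without knockout replicate 1 and 2, and 4631 without overexpression replicate 3. The scaled count of 4931 went to 2708 and 2756 without KY replicate 1 and 3 and to 3225 without knockout replicate 1.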

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

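In this part the tests of a different background, of a transgene effect, of linked blocks and of ChlH read reassignment were chosen after the result was seen, as was median scaling. Also set after their values were seen were the judging of the ChlH sum on both scales, the minimum of 5 other pairs, and equal totals in place of median scaling for the offset, whose share of 48.0% centring largely fixes. The splits that keep overexpression and KY apart were likewise run after the drawn ones had been seen. The effects of the overexpression and knockout libraries differed, by a test of the difference itself, in 2750 genes and in 8 of the gene lists. Beside Nitab4.5_0005031g0050 (5.51), the positive differences named were translation initiation factor 1A, Nitab4.5_0003779g0110 (5.24), the ubiquitin-conjugating enzyme Nitab4.5_0003779g0060 (5.51), the elongation factor G-type gene Nitab4.5_0000147g0070 (4.96) and ChlH, Nitab4.5_0005195g0040 (5.24). The negative ones were the transposase Nitab4.5_0000386g0150 (-4.17), the MADS-box gene Nitab4.5_0014584g0010 (-3.30), the NB-ARC resistance-type gene Nitab4.5_0021935g0010 (-2.85), the CAAX protease Nitab4.5_0000804g0170 (-3.11) and the dikinase-type gene Nitab4.5_0000059g0230 (-4.62). The remaining chelatase differences were 2.97 for the D-type copy Nitab4.5_0000733g0210, -1.49 for Nitab4.5_0001663g0090 and -2.25 for the ChlH copy Nitab4.5_0010636g0020. Every named difference had the sign of K326 minus KY (5.70 for ChlH, Nitab4.5_0005195g0040, and -3.32 for the MADS-box gene Nitab4.5_0014584g0010). Of the 2750 genes 1017 (37.0%) were also called in K326 against KY in that direction, and 2988 of 4931 (60.6%) with median scaling. The difference itself contains K326 minus KY, so some of this overlap arises by construction. All 8 lists lost their call with an estimated correlation (adjusted p from 0.313 to 0.831): cell division, abscisic acid, vascular, cytosolic ribosomal and pathogenesis-related genes were on the positive side, and Calvin cycle, carotenoid and heat shock genes on the negative side. On median-scaled values the 3 negative lists (adjusted p = 0.0992, 0.205 and 0.205) and the pathogenesis-related genes (0.264) lost their calls, so no list on the negative side kept its call.

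The overexpression libraries followed K326, not KY, at genes on in one wild type and off in the other: at least 94% of the 100 genes were in the K326 state in each library. RNA or chromosomes of both cultivars in these libraries are argued against for most of these genes, since those on only in KY had a median of at most 0.211% of the KY level. An exception was Nitab4.5_0003627g0060, at 0, 3.03 and 6.56 TPM in overexpression replicates 1, 2 and 3 against 12.33, 4.82 and 3.67 in KY. The explanation is therefore not argued against for every gene. An effect of the transgene within KY plants that is unrelated to K326 is argued against for genes that are on or off. By the same limits, 57 genes were on in overexpression and off in KY, and 15 were the reverse. Between overexpression and K326 these counts were 0 and 1, where an unrelated effect would have left differences from K326 as well. Smaller changes were not tested in this way. At most 7.69% of the genes on only in KY stayed at 1 TPM or more, but this restates the pattern itself. A candidate explanation that remains is that the overexpression and KY libraries differ in genetic background, through the line's parentage, different seed stocks or a label. The level of NtCISZOG, which could bear on the labels, was not analysed here.

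Genes on in K326 were at or near 0 in KY, the ChlH copy Nitab4.5_0005195g0040 nearly so. Of the 87 genes, 45 shared the number before the g of their identifier with another of them, against a median of 2 and a maximum of 10 in random sets (permutation p = 1e-04, the smallest that 10000 draws can give), so linked blocks missing or diverged in KY may lie behind part of the pattern. One such number held 6 of these genes among 9 expressed in K326, the D-type chelatase copy included. Reassignment of ChlH reads to the other copy would leave the sum of both level, but the lowest KY sum was 1.36 times the highest K326 sum as deposited and 1.72 times after median scaling, more than 1 K326 SD above it on both scales, and only the second passes the bound of 1.5 set for it, so this stays open. The same ratio for the D-type copies was 0.977 as deposited, with the groups overlapping, and 1.24 scaled, more than 1 K326 SD above, while partners in the only 2 other pairs with one description went opposite ways (-0.69 and 0.92 log2, median 0.11), which decides nothing.

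Most called genes of K326 against KY lay on the higher side as deposited. The 10 highest listed genes took shares that would shift the rest by 0.0262 log2 only, against a median shift of 0.39. This argues against a few listed genes taking more of the KY values. The listed values need not hold the whole library, so the test says nothing about transcripts that are not listed. Scaling every library to the same total left 70.4% of the calls higher (5385 higher and 2266 lower), and median scaling left 48.0%. An offset of whole libraries in the deposited values could therefore account for part of the imbalance, and the totals did not show how large a part. A real difference in RNA composition between the cultivars stays open and was not tested.

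Splits of 3 against 3 libraries number 10, too few to exclude chance. The real count and the highest of the other splits were 6 and 6 genes for knockout against K326, 5721 and 0 for overexpression against KY, and 8441 and 0 for K326 against KY. For lists they were 3 and 10, 11 and 8, and 11 and 11. In the knockout comparison 9 of the 10 splits gave as many lists. For the difference, the 90 of 99 drawn splits that mixed the overexpression and KY libraries gave at most 1 gene, so such draws only separate overexpression from KY. The splits that keep those libraries apart and regroup the knockout and K326 number 20 with the real one, too few for a share under 0.05. The real count was 2750 and the highest other 4901, and 5 of the 20, the real one included, gave as many. As many as 4 chelatase calls came from 10 of the 100 draws, the real one included. The other 9 kept the overexpression and KY libraries apart, and so kept the comparison that gave these calls. The 90 draws that mixed those libraries gave 0. This count therefore cannot decide about chance for the chelatase calls.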

How the results depend on the processing

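In this part median scaling, alone, with the block or with the other wild type, and the other wild type for lists were chosen after the data were seen, and the rest were planned. The 4 chelatase calls against KY stayed at 4 with quantile normalization, no filter, the replicate block, median scaling, the 6 libraries alone and each library left out, and with K326 as the reference 0 were called. The 6 knockout genes became 0 with quantile normalization, 0 with median scaling, 13 without a filter, 3 with a pseudocount of 0.1, 38 from the 6 libraries alone, 0 to 12 with libraries left out, and 18754 with KY as reference (10215 scaled). The 5721 overexpression genes became 11112 with quantile normalization, 10827 with median scaling, 3705 at a mean of at least 5, 3040 at a fold of at least 2, 12143 with K326 as reference (3199 scaled), and 3310 to 5932 with libraries left out. The 8441 wild-type genes became 5147 at a mean of at least 5 and 3272 at a fold of at least 2, both smaller by construction, and 3013 to 9329 with libraries left out. The 2750 differences became 5122 with quantile normalization, 4931 with median scaling and 1135 to 4631 with libraries left out (2708 to 6532 scaled). Lists called, 3, 11 and 11 for knockout, overexpression and wild types, became 0, 0 and 0 with an estimated correlation and 0, 5 and 4 with fry. Knockout lists numbered 6 with median scaling, 8 with KY as reference and 0 to 8 with libraries left out, and overexpression lists numbered 6 with K326 as reference; the other settings left 8 to 12 lists in the last 2 comparisons. Replicate numbers of the labels did not pair the libraries throughout, with correlations of deviations from -0.0730 to 0.320, and not every library correlated best with its own number. Replicate 2 did so between knockout and K326 (0.320, other numbers at most -0.0725) and between K326 and KY (0.224, others at most -0.0255). It did not between overexpression and KY (-0.00856, others up to 0.0310). The raw data number KY 3 as 4 and overexpression 1, 2 and 3 as 2, 3 and 4, a pairing not tested. With the replicate block the calls were 17, 5254, 7387 and 2126 for knockout, overexpression, wild types and the difference, and with median scaling added 0, 10544, 7546 and 4577; the lists were 3, 11 and 10. Chelatase genes in the knockout, none called, changed sign: with quantile normalization and median scaling Nitab4.5_0000733g0210 went to -0.042 and -0.049, Nitab4.5_0006237g0030 to -0.072 and -0.17 and Nitab4.5_0010636g0020 to -0.16 and -0.26. With libraries left out they ranged from -0.32 to 0.18 (Nitab4.5_0005195g0040), -0.076 to 0.22 (Nitab4.5_0006237g0030) and -0.33 to 0.30 (Nitab4.5_0010636g0020). Of the named calls under settings other than the reference, 250 of 250 values kept their call for overexpression (against K326 with median scaling 0 of 10 largest rises and 2 of 10 largest falls were called), 239 of 247 for the wild types, 154 of 154 for the difference and 26 of 66 for the knockout, where all 6 genes lost it somewhere. Except where construction is named, the cause was not tested. Count-based tools and normalizations were not run, since the values are not counts, and the zeatin O-glucosyltransferase result had no genes. Read depth is unknown, so its limit on low genes could not be set.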

Other observations

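In this part the gene lists, the K326 reference with median scaling and the single genes were all chosen after the data were seen. Against both wild types, with median scaling, the overexpression libraries differed in the same direction in 2032 genes, 1253 higher and 779 lower, against 313 and 254 for independent lists. As deposited the split was 354 higher and 2343 lower, so it turned with the scaling. Both comparisons use the same overexpression libraries, which alone raises the overlap, and its size without an effect was not computed. The count against K326 rested on single libraries, since 3199 genes went to 854 without overexpression replicate 2 and to 5241 without replicate 1, and to 1368 and 1018 without K326 replicate 2 and 3. Jasmonate genes (Tify repressors, lipoxygenases and allene oxide cyclase, which makes the jasmonate precursor) were higher than in K326 in 19 of 38 and lower in 1 (camera adjusted p = 5.6e-07; adjusted p = 0.357 with an estimated correlation), and higher than in KY in 21. As deposited 12 were higher and 9 lower than in K326. The allene oxide cyclase Nitab4.5_0004118g0110 stood at 130 ± 47.8 TPM against 43.2 ± 10.6 in K326 and 18.4 ± 4.65 in KY. Phloem protein 2-like genes led the vascular list, 12 higher and 1 lower of 36 against K326 (camera adjusted p = 5.8e-05; adjusted p = 0.0858 with an estimated correlation), with Nitab4.5_0000595g0040 at 114 ± 57.3 TPM against 7.70 ± 5.70 and 4.05 ± 1.20. SWEET sugar transporters, which export sugars from cells, were lower than in K326 in 16 of 31 and higher in 2 (camera adjusted p = 8.9e-08; adjusted p = 0.437 with an estimated correlation), among them Nitab4.5_0010626g0010 (9.55 ± 3.98 TPM against 53.2 ± 16.4 in K326, 32.6 ± 3.13 in KY and 65.0 ± 3.99 in the knockout).

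Several single genes followed the same pattern. The chlorophyllase Nitab4.5_0011519g0020 was higher than in K326 (22.7 ± 18.3 against 1.60 ± 0.649 TPM; scaled log2 change 3.51, limma adjusted p = 0.0031), as was the Staygreen gene Nitab4.5_0011435g0010 (12.6 ± 12.8 against 2.43 ± 1.63). Their list, chlorophyll breakdown, had 2 higher and 0 lower of 23 against K326 with median scaling and was not called (camera adjusted p = 0.678), and 1 higher and 12 lower as deposited. The ammonium transporter Nitab4.5_0000841g0070 was lower (5.40 ± 3.55 TPM against 35.8 ± 2.68 in K326 and 25.0 ± 0.826 in KY). In the UDP-glycosyltransferase family 8 members were higher and 11 lower than in K326 with median scaling, and 3 and 58 as deposited. As deposited, the vascular list had 9 each way against K326. The 3 overexpression libraries spread widely at many of these genes, as the SDs show.

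Genes typical of the plastid genome, such as PsaA/PsaB, took 0.598 to 0.745% of the listed TPM in KY libraries, 0.233 to 0.546% in K326, 0.176 to 0.286% in the knockout and 0.563 to 1.32% in overexpression. The shares ran nearly opposite to the log2 factors of median scaling, also within groups except for KY replicates 1 and 3. Overexpression replicate 2 had 1.32% at -0.862 and replicate 3 had 0.563% at -0.113. K326 replicate 1 had 0.546% at -0.0147 and replicate 2 had 0.233% at 0.486. A group difference could thus not be told apart from the library offsets. These genes were lower in K326 than in KY in 16 of 41 and higher in 0 (camera adjusted p = 3.1e-25, adjusted p = 0.355 with an estimated correlation, 13 and 0 with median scaling). After median scaling they were higher in overexpression than in K326 in 19 and lower in 0 (camera adjusted p = 7.8e-14, adjusted p = 0.479 with an estimated correlation). In overexpression against KY 0 of 41 were called (median log2 change 0.02, camera adjusted p = 0.340). In the knockout 0 of 41 were called, with a median log2 change of -0.32 (8.1e-18; adjusted p = 0.454 with an estimated correlation). Ribosomal proteins of the archaeal and eukaryotic type were higher in K326 than in KY in 191 of 288 and lower in 4 (79 and 13 with median scaling; 8.0e-09; adjusted p = 0.971 with an estimated correlation). Clock pseudo-response regulators and GIGANTEA were higher in K326 in 6 of 8 (camera adjusted p = 0.00884; adjusted p = 0.887 with an estimated correlation) on both scales. The time of day of sampling was not given in the sources used here.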
